A study of Mus musculus with 9 samples.

How the data were processed

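RNA from white adipose tissue of male C57BL/6 mice was enriched for poly(A) RNA, made into barcoded Ion Torrent libraries and sequenced on an Ion Proton instrument, per the labels' protocols. The submitters' processing notes name STAR 2.5.2 and the genome build mm9 without a role for either. How reads were counted, the annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here, so rows that share reads with near-identical copies, overlapping or antisense sequences are uncertain. The values deposited by the authors are raw counts of reads, in one table with a row for each of 39130 GI numbers and a column for each of the 9 libraries. All values are whole numbers, and 0 rows are at zero in every library. The 6 largest counts are all multiples of 10, so they carry fewer digits than the rest. Column names hold the sample numbers of the labels' titles, which is how columns were assigned to groups.

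The labels give 3 groups of 3 mice without batch or pairing, and replicate numbers follow only the order of the records. Beyond the number per group, the labels do not say how animals and libraries correspond, so p-values measure the spread between these libraries. No pair of libraries in a group was a duplicate: the smallest chi-square per degree of freedom between 2 libraries of a group was 18.3.

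Rows were tested when they reached a CPM equivalent to 10 counts in a library of median size in at least 3 libraries and 15 counts in all, which left out 10299 rows. Libraries were scaled by trimmed means of log ratios (TMM, trimming a fraction of 0.3 of log ratios and 0.05 of mean levels at each end). A group-means model over all 9 libraries was fitted with limma-voom (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts relative to the scaled library total over tested rows. A value of 1 CPM corresponds to between 26.7 and 42.6 counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

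The test fixed before the data were examined was a quasi-likelihood test of negative binomial counts, and it was not used for the reported results. Limma-voom, one of the alternatives fixed at that time, took its place because the automated check of the table's unit could not read this file, and count models were not permitted without that check. The values were therefore inspected directly but not checked automatically against the unit of counts. The quasi-likelihood test had been tried once outside the reported tables and likewise called no row in any of the comparisons, with more rows than limma-voom at an unadjusted p under 0.05 in each, so the replacement was made with that outcome known.

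The rule for rows named in the text was fixed before the data were examined. Where too few rows passed the test, it took those with the smallest unadjusted p among rows with a mean of at least 5 CPM over the 9 libraries and no overlap between the groups compared. As rows carry no gene names, 1 row per direction and comparison was printed. For the same reason the 38 gene lists fixed beforehand, among them markers of other cell types, were not tested, and no gene of interest could be looked up; none of the GI numbers matched the gene identifiers of the reference table at hand. No genome coordinates are given.

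The procedure was tested on simulated counts with 200 changed rows among 28831. With the spread of the real libraries, it recovered 10% of 2-fold, 32% of 4-fold and 64% of 8-fold changes in the diet comparison, 4%, 46% and 58% in the comparison of B-LGND2 with vehicle on the high fat diet, and 10%, 34% and 52% in that of B-LGND2 with the normal diet. With a dispersion of 0.05 it recovered 62%, 44% and 50% of 2-fold changes in these comparisons and 100% of 4-fold changes in each. Among the unchanged rows it called 7, 3 and 9 with the spread of the real libraries and 9, 11 and 12 with a dispersion of 0.05. Simulated libraries were drawn independently for each row, so the structure shared between the real libraries was absent. The spread was capped for the most variable rows, and changed rows were drawn only from the more abundant ones. These shares therefore do not measure the power of the real design over all tested rows. Alternatives comprised other scalings and filters, fits on only the groups compared, library quality weights, a fold threshold, and leaving out each library in turn. Added after the data were seen were limma-trend, a fit without normal diet vehicle replicate 2 and high fat diet B-LGND2 replicate 2, and a fit without the 115 rows that set normal diet vehicle replicate 2 apart.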

Results

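Messenger RNA was measured by sequencing in white adipose tissue, the fat-storing tissue, of male C57BL/6 mice, a common inbred laboratory strain, after 9 weeks of feeding and treatment. The 9 libraries fell into 3 groups of 3: mice on a normal diet given vehicle, mice on a high fat diet given vehicle, and mice on a high fat diet given B-LGND2, which the series title places among ligands of estrogen receptor beta, a nuclear hormone receptor. The total count per library lay between 30067542 and 43129222 reads. Each row of the deposited table is a sequence named by a GI number, an older numbering of sequence records, and the files do not pair these numbers with gene names. Values are therefore given per row, and at most the leading row in each direction is identified for a comparison. The tests covered 28831 of the 39130 rows.

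The libraries did not separate by group. The mean correlation of log2 CPM, the count scaled to the size of its library, across rows was 0.907 over the 9 pairs of libraries from the same group and 0.898 over the 27 pairs from different groups; rows are not independent replicates. The groups accounted for 29.2% of the spread between libraries, and 90 of the 280 possible partitions into 3 groups of 3 gave at least as large a share (exact permutation p = 0.321, one-sided). Normal diet vehicle replicates 1 and 3 correlated at 0.982 and high fat diet B-LGND2 replicates 1 and 3 at 0.980, so these pairs followed the groups. Normal diet vehicle replicate 2 was closest to high fat diet B-LGND2 replicate 1, at 0.961. Within the high fat diet vehicle group the correlations were 0.842 to 0.912, and replicate 2 was closest to high fat diet B-LGND2 replicate 1, at 0.943. High fat diet B-LGND2 replicate 2 correlated with replicates 1 and 3 of its group at 0.923 and 0.921. Its correlations with normal diet vehicle replicates 1 and 3 were 0.929 and 0.931. High fat diet vehicle replicate 1 and high fat diet B-LGND2 replicate 2 were closest to each other, at 0.971.

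**Figure D1:**
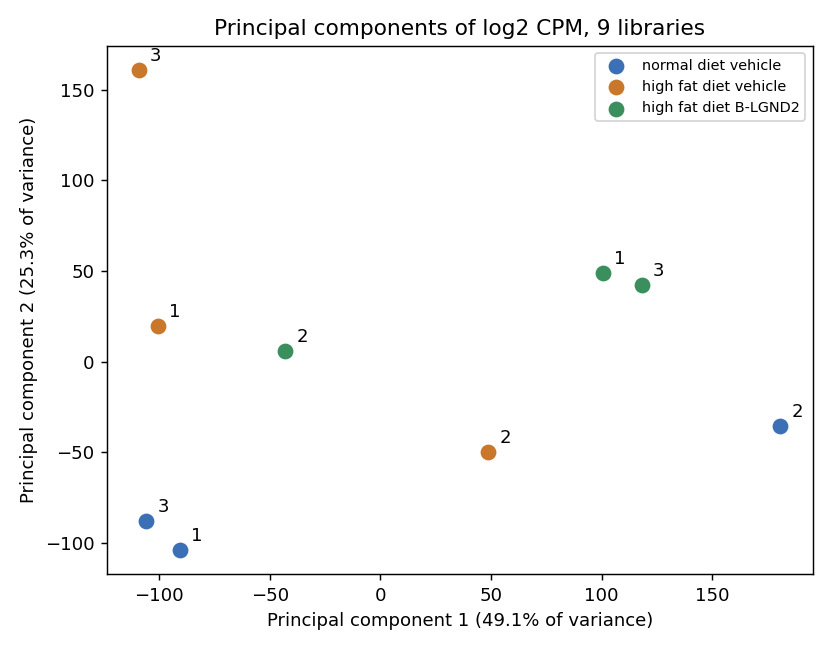
Principal components of log2 CPM over the tested rows, with component 1 (49.1% of variance) on the x axis and component 2 (25.3%) on the y axis; each point is a library, coloured by group and numbered by replicate. Normal diet vehicle replicate 2 lies at 180.8 on component 1, while replicates 1 and 3 of its group lie at -90.6 and -105.7.

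The first comparison asked how the high fat diet changed expression in vehicle-treated mice. Rows named in this and the following comparisons had a mean of at least 5 CPM and no overlap between the groups compared. Both were conditions of the choice. Among such rows higher on the high fat diet, GI 115392137 had the smallest p. It was at 32.5 ± 8.15 CPM (SD, n = 3) on the high fat diet and 5.86 ± 3.69 CPM (SD, n = 3) on the normal diet. Its fitted log2 difference was 2.65 ± 0.40 (SE), and by the rule all 3 high fat diet vehicle libraries were above all 3 normal diet vehicle libraries. The leading row in the other direction was GI 149251591, at 13.9 ± 4.04 CPM (SD, n = 3) on the high fat diet against 53.6 ± 8.19 CPM (SD, n = 3) on the normal diet, a log2 difference of -1.97 ± 0.26 (SE). In all 3 normal diet vehicle libraries this row was higher than in any high fat diet library, the lowest value being 48.8 CPM. Neither row passed the test, with an adjusted p of 0.601 for both (limma-voom, Benjamini-Hochberg). Without normal diet vehicle replicate 2 both passed, with adjusted p-values of 0.0259 and 0.0395 in limma-voom, in a range over all alternatives of 0.0259 to 0.944 for GI 115392137 and 0.0395 to 0.944 for GI 149251591. Across all tested rows, limma-voom called 0 rows higher and 0 lower on the high fat diet at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1240 rows higher and 1069 lower, where chance alone gives 1442 in all. Neither the balance nor the total was stable. By total counts alone, 2650 rows were higher and 206 lower. There were 3735 higher and 1337 lower without high fat diet vehicle replicate 2, and 2212 and 3236 without normal diet vehicle replicate 2. The total was 997 without normal diet vehicle replicate 3 and 1428 without high fat diet vehicle replicate 3, both below the chance value. The 3 libraries of one group did not overlap those of the other in 11.7% of rows, against 10% by chance. Of the 10 possible splits of these 6 libraries, 3 gave at least as many such rows, the real one included. The count depended on normal diet vehicle replicate 2: without it, the same test called 63 rows higher and 197 lower. That fit kept 2 normal diet libraries, which correlated at 0.982. Leaving out the library that stood apart lowers the spread by itself, so the rise does not show an effect of diet.

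The second comparison asked how B-LGND2 changed expression in mice on the high fat diet. GI 21704173 was at 101.8 ± 19.0 CPM (SD, n = 3) with B-LGND2 and at 20.6 ± 2.18 CPM (SD, n = 3) with vehicle, a log2 difference of 2.29 ± 0.20 (SE), or 4.88-fold. Its level was 32.03 ± 1.55 CPM (SD, n = 3) on the normal diet, and the 3 libraries with B-LGND2, at 116.5, 80.4 and 108.4 CPM, were above the other 6 libraries. It missed the threshold in limma-voom, with an adjusted p of 0.0659. It passed under 7 of 20 alternatives, among them leaving out normal diet vehicle replicate 2 (limma-voom adjusted p 0.0323), in a range of 0.0096 to 1. The leading row in the other direction, GI 31542808, was at 7.28 ± 2.04 CPM (SD, n = 3) with B-LGND2, 42.1 ± 13.3 CPM (SD, n = 3) with vehicle on the high fat diet and 4.92 ± 4.19 CPM (SD, n = 3) on the normal diet. Its log2 difference between B-LGND2 and vehicle was -2.52 ± 0.48 (SE), with an adjusted p of 0.815 in limma-voom. The row GI 115392137, which led the diet comparison, was at 11.4 ± 1.64 CPM (SD, n = 3) with B-LGND2. Across all tested rows, limma-voom called 0 rows higher and 0 lower with B-LGND2 than with vehicle on the high fat diet. At an unadjusted p under 0.05 there were 1010 rows higher and 488 lower, 1498 in all against 1442 by chance. Neither the total nor the direction was stable: there were 1193 higher and 3020 lower without high fat diet vehicle replicate 2, 635 and 305 without high fat diet B-LGND2 replicate 1, 274 and 221 without replicate 3 of that group, and 663 and 662 without the 115 rows described at the end. The groups did not overlap in 13.8% of rows, against 10% by chance, and 3 of the 10 splits, the real one included, gave at least as many such rows. Without normal diet vehicle replicate 2, which belongs to neither group but enters the filter, the scaling and the estimate of the spread, 1 row was called higher and 7 lower, with 1817 higher and 996 lower at an unadjusted p under 0.05.

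**Figure D2:**
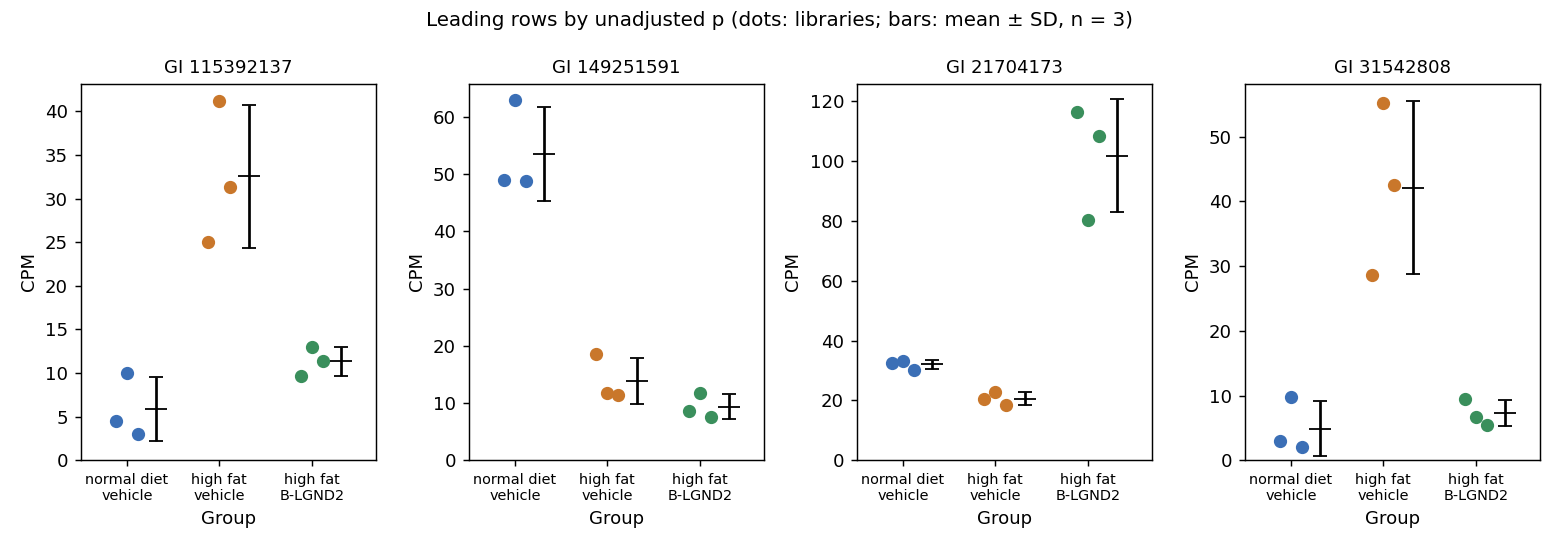
CPM on the y axis of the 4 leading rows in each group on the x axis, where dots are libraries and the black bar is the mean with its SD (n = 3). GI 21704173 lies between 80.4 and 116.5 CPM in the libraries with B-LGND2 and at 33.3 CPM or less in the other libraries; none of the 4 rows passed the test after adjustment with all 9 libraries.

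The third comparison set high fat diet B-LGND2 against the normal diet with vehicle, so that diet and ligand differ together. The leading rows had both been named above. GI 21704173 was higher by 1.65 ± 0.19 on the log2 scale (SE), and GI 149251591, at 9.34 ± 2.17 CPM (SD, n = 3) with B-LGND2, had a log2 difference of -2.55 ± 0.27 (SE). The adjusted p was 0.179 for both in limma-voom, which called 0 rows higher and 0 lower across all tested rows. Without normal diet vehicle replicate 2 both rows passed in limma-voom, with adjusted p-values of 0.0146 for GI 21704173 (range over the alternatives 0.00112 to 0.987) and 0.0073 for GI 149251591 (0.000845 to 0.929). At an unadjusted p under 0.05 there were 1593 rows higher and 1305 lower, against 1442 in all by chance; by total counts alone there were 3292 and 526. The total of 2898 fell to 1530 and 1169 without normal diet vehicle replicates 1 and 3, and to 1671 and 1411 without high fat diet B-LGND2 replicates 1 and 3, where 1169 and 1411 lie below the chance value, and was 7810 without normal diet vehicle replicate 2. The groups did not overlap in 16.9% of rows, against 10% by chance. These were 4859 rows, and 2 of the 10 splits of the 6 libraries gave at least as many: the real one and a split with 12288. Without normal diet vehicle replicate 2, 738 rows were called higher and 1087 lower, so the count of 0 depended on that library. As in the diet comparison, leaving it out lowers the spread by itself, so the rise does not show an effect.

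The difference between diets and the difference between B-LGND2 and vehicle were set against each other across rows, to ask whether rows that differed with diet differed the opposite way with the ligand. Both use the high fat diet vehicle libraries with opposite sign, so a negative correlation arises without any effect. The observed Pearson r across rows was -0.41, and groups simulated without change gave -0.50 (range -0.53 to -0.47 in 100 draws). The simulation leaves out the structure between libraries: in 100 draws with the group labels of the real libraries shuffled, r ranged from -0.90 to 0.28 with a median of -0.53, and 71 draws were at or below the observed value. The covariance was -0.26 observed and -0.28 simulated (range -0.31 to -0.26). With shuffled labels it ranged from -1.29 to 0.21 with a median of -0.25, and 47 draws were at or below the value for the labels as given. Both observed values lay within the range of the shuffled draws, so neither sets an opposite change apart from the shared libraries. The shared group was not split, since one side would have held a single library. Without normal diet vehicle replicate 2, r was 0.0068, for which no value without change was simulated.

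The normal diet vehicle group contained a set of 115 abundant rows that were nearly absent from a single library. They were chosen after the values were seen, as those at 100 CPM or more in replicates 1 and 3 and at 1 CPM or less in replicate 2; 0 rows met the mirrored condition. The difference was not limited to this set: of the other tested rows, 1332 were higher and 2907 lower in replicate 2 by over 2 on the log2 scale. The 115 chosen rows took 10.8% of all counts in replicate 1 (95% Wilson interval 10.83 to 10.85%) and 11.3% in replicate 3 (11.27 to 11.29%), but 0.00306% in replicate 2 (0.00287 to 0.00326%). In the high fat diet vehicle libraries, which played no part in the choice, the share was 5.49%, 1.83% and 2.12%. With B-LGND2 it was 0.0168%, 3.50% and 0.0156%. The intervals cover counting error alone, since PCR copies are not independent molecules. Among the named rows, GI 149251591 was at 63.0 CPM in normal diet vehicle replicate 2 and at 48.9 and 48.8 CPM in replicates 1 and 3, and GI 21704173 was at 33.3 CPM against 32.5 and 30.3 CPM. In the other 2 named rows replicate 2 was the closest of its group to the high fat diet vehicle level, with GI 115392137 at 10.04 CPM against 4.49 and 3.05 CPM and GI 31542808 at 9.74 CPM against 2.92 and 2.10 CPM.

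**Figure D3:**
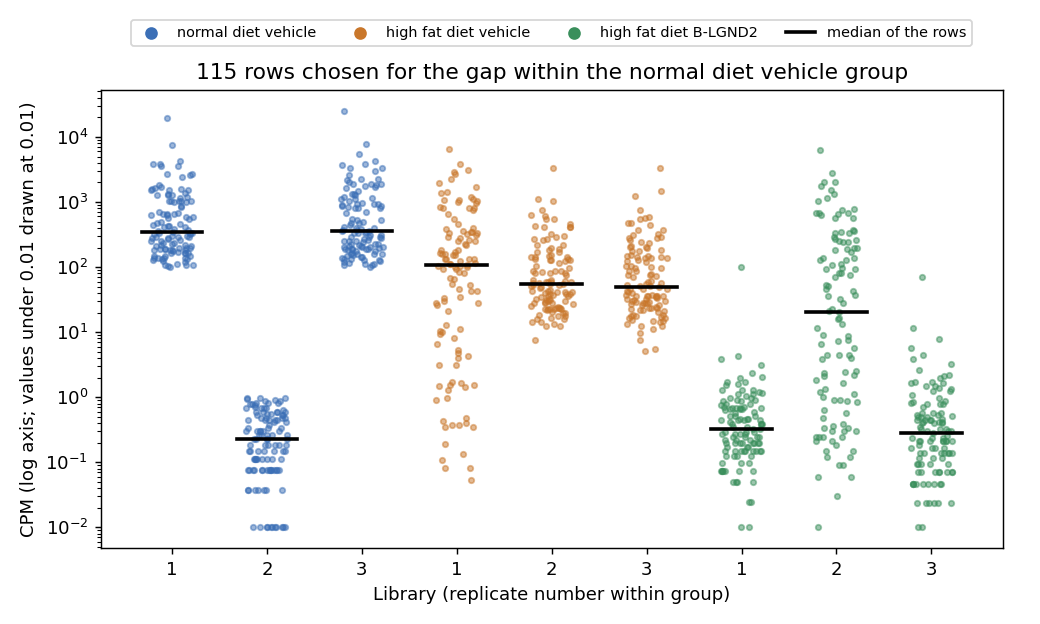
CPM on a log axis of the 115 rows in each of the 9 libraries, numbered by replicate within their group on the x axis; each dot is a row and the black line is the median. The median was 345 and 358 CPM in normal diet vehicle replicates 1 and 3 and 0.225 CPM in replicate 2, a gap that follows from how the rows were chosen, and between 0.281 and 108 CPM in the other 6 libraries.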

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

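The fits with limma-trend, without normal diet vehicle replicate 2 and high fat diet B-LGND2 replicate 2, and without the 115 rows were chosen after the data were seen. Of 126 recomputed counts of called rows, 106 stayed at 0 and 20 did not; the 6 with a 2-fold threshold could only be 0. B-LGND2 against vehicle on the high fat diet gave 1 higher row under scaling by total counts alone, under the filter of 5 CPM in 3 libraries, with the 50 most abundant rows left out of the scaling and with limma-trend, 2 higher with library quality weights, and 3 lower with only the libraries of the 2 groups compared. Quality weights gave 6454 higher and 6224 lower rows for B-LGND2 against the normal diet. Weights were 2.40 to 3.15 for replicates 1 and 3 of both groups but 0.187 (normal diet) and 0.628 for replicate 2. Replicates 1 and 3 thus dominated. The rows called with weights included 1812 of the 1825 rows called without normal diet vehicle replicate 2, in the same direction. The rest were not tested with all 9 libraries. Both fits give that library little or no weight, so the overlap is not independent support. Without normal diet vehicle replicate 2 and high fat diet B-LGND2 replicate 2 together, limma-voom called 67 higher and 206 lower rows for diet, 23 and 59 for B-LGND2 on the high fat diet, and 1920 and 1774 for B-LGND2 against the normal diet. Leaving out each library in turn gave 0 to 63 higher and 0 to 197 lower rows for diet, 0 to 1 and 0 to 7 for B-LGND2 on the high fat diet, and 0 to 738 and 0 to 1087 for B-LGND2 against the normal diet, the highest in each case without normal diet vehicle replicate 2 and 0 without any other library. The correlation between both differences ranged from -0.69 to 0.0068 when each library was left out, with -0.69 without high fat diet vehicle replicate 2 and 0.0068 without normal diet vehicle replicate 2. It was 0.056 with quality weights and 0.119 without normal diet vehicle replicate 2 and high fat diet B-LGND2 replicate 2 together. The cause of these changes was not tested. Scaling by total counts alone moved the median log2 difference of all rows from 0.05 to 0.29 for diet and from 0.07 to 0.24 for B-LGND2 against the normal diet. No named row changed direction in 120 recomputed values, and 17 of them passed the threshold. The adjusted p of GI 21704173 for B-LGND2 on the high fat diet ranged from 0.0096 to 1 over its alternatives. The negative binomial count models, the gene list tests and their alternatives were not run for these tables. The labels pair no libraries, so no paired analysis was possible.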

Other observations

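All tests in this part were chosen after the data were seen. For the reading of a label swap on rows that set B-LGND2 apart, only the bounds were written before its result.

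Replicate 2 of both vehicle groups had its highest correlation with high fat diet B-LGND2 replicate 1, at 0.961 for the normal diet and 0.943 for the high fat diet. Normal diet vehicle replicate 2 stood apart from replicates 1 and 3. On the 260 rows called for diet without it, it lay nearer to the high fat diet vehicle mean than to its own group in 253, and on 1812 of the 1825 rows called for B-LGND2 against the normal diet, those also tested with all 9 libraries, it lay nearer to B-LGND2 in 93.8%; these rows were called without it, on 2 libraries of its group. Crowding by the 115 abundant rows can shift other rows by 0.173 on the log2 scale, yet 37.8% of other rows differed by over 1 (8.70% between replicates 1 and 3), which argues against it. A swap with high fat diet B-LGND2 replicate 2 may account for part of the pattern: on 50 rows chosen on the other 7 libraries to set B-LGND2 apart, none passing adjustment, that library lay with B-LGND2 in 58% and normal diet vehicle replicate 2 in 68%, but held-out high fat diet vehicle libraries lay with their own group in 16 to 64% of 50 such rows, so these shares decide little. On 623 rows that set the normal diet apart, all passing adjustment, the B-LGND2 library lay with the normal diet in 5.94% and normal diet vehicle replicate 2 in 1.44%. A swap would give a high share for the B-LGND2 library. The low share cannot decide, as the rows were chosen on 2 normal diet libraries and no further library of undoubted label shows what share to expect. The split of libraries that makes this exchange, described below, called 3609 rows against 0 for the labels as given. A swap stays open, as does a difference between animals, and no biological explanation was tested.

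The 115 rows varied between libraries within each group, from 0.00306 to 11.3% of counts on the normal diet, 1.83 to 5.49% on the high fat diet with vehicle and 0.0156 to 3.50% with B-LGND2; a difference between groups was not tested. Total counts of the normal diet vehicle libraries differed by 1.25-fold at most, which argues against depth. Between high fat diet vehicle replicates 1 and 2 the SD of the log2 ratio over these rows was 4.21. All 1000 sets of rows matched on expression were below it (highest 1.31), which argues against one added source of RNA with a fixed profile in both libraries. Between replicates 1 and 3 the SD was 4.27. Between replicates 2 and 3 it was 0.627, below the matched median of 1.04, and 994 of 1000 matched sets had at least this SD. Replicates 2 and 3 thus had a similar profile over the rows. The argument therefore rests on replicate 1, and one source in differing amounts in the remaining libraries was not tested. Matching was on mean expression alone, while the 115 rows were chosen for a large gap between libraries. Several sources of RNA, such as neighbouring tissue taken with the fat, stay open, since rows without gene names allow no test of markers.

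The 10 possible splits of 6 libraries cannot give a share under 0.05. The real split called 0 rows in each comparison, so that all 10 splits gave as many by construction and the count of calls decides nothing. The highest other split called 1 row for diet, 0 for B-LGND2 against vehicle on the high fat diet and 3609 for B-LGND2 against the normal diet. Rows at an unadjusted p under 0.05 were at least as many as in the real split in 5, 3 and 2 of the 10 splits, the real one included. The highest other split gave 7602, 4590 and 8749 such rows. The split with 3609 called rows had normal diet vehicle replicates 1 and 3 and high fat diet B-LGND2 replicate 2 on one side. A swap of labels between that library and normal diet vehicle replicate 2 would give this grouping. The split with 7602 rows exchanged normal diet vehicle replicate 2 with high fat diet vehicle replicate 1. That with 4590 exchanged high fat diet vehicle replicate 2 with high fat diet B-LGND2 replicate 2. Every split other than the real one exchanges 1 library of each group. The count of 3609 points to a structure of the libraries other than the labelled groups, but cannot tell a swap from another such structure.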
